A study of Mus musculus with 171 samples.

How the data were processed

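The measurement was single-cell RNA sequencing of mouse ICM, EPI and PrE cells, in which 1 deposited sample is 1 cell. The authors deposited a table of counts per gene, whole numbers with no normalization, with 171 columns of cells and 49671 gene rows named by Ensembl identifiers; all columns were used. Per the submitters' processing notes, STAR, HTSeq and the mouse build mm10 were used. Their versions, the counting settings, the strand setting and the library method are not given in the sources used here. Reads of overlapping, antisense, paralogous and pseudogene copies may therefore be shared, and the processed pseudogenes Gm21399 and Gm8355, called between the stages, are uncertain for that reason. PCR copies without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Gene names, types and positions came from the GENCODE vM21 annotation of the same build; 49326 rows matched, and the 345 others held 0.0101% of counts. No pair of cells had identical counts.

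Stage, genotype, embryo, cell and a letter come from the sample titles, and the lineage from the sample type label. The first number after the genotype was taken as the embryo, which the labels do not state in words. The meaning of the letter is not given in the sources used here. Cells are not replicates, so raw counts were summed per embryo and lineage over all cells (24 sums of 17 embryos). The sums held 8117787 to 88167705 counts in MUT ICM and 28675202 to 122331780 in WT ICM. No cell was removed from the sums, no cells were clustered, and doublets were not searched for. Embryo sex was called male where the summed Y-linked counts (4 genes) exceeded Xist. A rule based on Y-linked CPM alone was tried before, called E3.5 MUT embryo 10 male although Xist far exceeded its Y-linked reads, and was replaced after the data were seen. At E3.75, Y-linked reads exceeded Xist in 31 of 31 cells of male and 0 of 21 cells of female embryos, and at E3.5 in 35 of 40 and 1 of 79.

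Each comparison was fitted to its own groups with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; TMM scaling, filterByExpr with a minimum count of 10, robust dispersion), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values of named genes are TMM-scaled and given as mean ± SD over embryos. The SE of an edgeR log2 fold change is its absolute value over the square root of the quasi-likelihood F. It thus restates the test and is not a separate estimate of spread. Differences of genotype effects were tested as interaction contrasts. The 14 gene lists were STAT3 targets, mitochondrially encoded mRNAs, nuclear OXPHOS subunits, TCA cycle and α-ketoglutarate metabolism, glycolysis, DNA methylation machinery, imprinted genes, naive pluripotency and EPI markers, formative and primed markers, PrE markers, trophectoderm markers, p53 targets and apoptosis, FGF/ERK targets, and immediate early and heat shock genes. Shared members were Gbx2, Klf4, Klf5 and Tfcp2l1 (STAT3 and naive), Dnmt3a and Dnmt3b (DNA methylation and formative), Dppa3 (DNA methylation and naive) and Egr1 and Ier2 (FGF/ERK and immediate early). Lists were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, and with fry, which tests whether a list moves one way, adjusted over the 14 lists of a comparison. Camera at the preset correlation called 4 lists in the ICM, 3 in EPI, 4 in PrE, 5 and 3 between the lineages in WT and MUT, 4 and 6 between the stages, and 3 and 7 in the lineage and stage interactions, and fry called 1, 1, 0, 0, 3, 4, 3, 0 and 0. Single values per embryo were tested with exact two-sided permutation tests (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3), and figures were drawn with matplotlib 3.10.9. The 6 quality values tested in each lineage were not adjusted for their number; besides mitochondrial mRNA in the ICM they gave exact p values from 0.143 to 0.971.

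The groups, comparisons, lists, named-gene rule and most alternatives were fixed before the data were examined. Named genes were Stat3, then in each genotype comparison the 8 largest rises and 8 largest falls among genes past the threshold, with at least 10 CPM in 1 group and the same sign in every fit without an embryo (no gene qualified), and in each list up to 4 members past the threshold, or else the 2 with the smallest p. In lineage and stage comparisons the rule took 5 rises, 5 falls and up to 3 members per list, and in interactions the 5 smallest adjusted p values. For a gene with no counts in a group, the fold is a bound from a floor of 3 counts over the group.

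Alternatives were DESeq2's size factors (RLE), no low-count filter, DESeq2 (1.42.0), limma-trend on embryo means of log2(CPM + 1), which weights cells equally, removal of 7 cells below the stage median by 3 median absolute deviations in depth or genes detected (5 MUT and 2 WT ICM cells), removal of sums of 1 cell, each embryo left out, the title letter, the embryo number and embryo sex as covariates, and limma-voom on single ICM cells with the embryo as a random block, with and without the letter. Camera on the single-cell fits had no embryo block and took cells as replicates. For sums, the letter could be fitted only at E3.75. Fits without genes on X and Y, and without 8 cells with more than 10 CPM each of Y-linked genes and Xist, were added after the data were seen. Median fold changes of X-linked and autosomal genes were compared with and without embryo sex as a covariate.

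By the title numbers, EPI and PrE sums with the same number come from the same embryo. The deviations of EPI and PrE from their group means correlated within embryos by 0.0427 to 0.134 in MUT (mean 0.0814) and by 0.0806 to 0.153 in WT (mean 0.125). Between embryos the means were −0.0256 in MUT and −0.0626 in WT. Deviations from a group mean cancel over the group, so these follow nearly from the values within embryos and are no separate baseline. The fits with the embryo as a block are given with the lineage results they change.

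On simulated counts with the real means and depths, edgeR recovered, of 100 genes changed by 4-fold and by 32-fold, 11 and 91 in the ICM comparison (11889 genes, 3 false calls), 24 and 75 in EPI (11618, 3), 23 and 69 in PrE (11111, 4), 11 and 70 between lineages in WT (12145, 2), 23 and 70 in MUT (10274, 6), 27 and 93 between stages in WT (13491, 4), 9 and 84 in MUT (11278, 4), and 4 and 52 (13775, 1) and 4 and 57 (15368, 2) in the lineage and stage interactions. DESeq2 recovered 29 and 96 in the ICM with 62 false calls and 56 and 90 in EPI with 114. Limma-voom and limma-trend were run on a separate simulation of single cells, with an assumed embryo effect and a fixed dispersion for all genes. There limma-voom recovered 23 and 100 in the ICM with 18 false calls. Limma-trend recovered 12 and 99 in the ICM with 6 but 0 and 28 in EPI with 0. These values cannot be ranked against those of edgeR and DESeq2. In the other 7 comparisons DESeq2 made 87 to 224 false calls. The counts given to edgeR and DESeq2 were drawn with the dispersions that edgeR had estimated, so they favour edgeR. Changed genes were taken from those with a mean of at least 10 CPM, so the recovery does not cover less abundant genes. Simulated lists of 40 genes raised 2-fold had camera p values from 7.03e-16 to 9.7e-05, and unchanged lists from 0.203 to 0.91, over the 9 comparisons. Genes were drawn independently of each other, so these lists cannot show how often camera calls lists of correlated genes falsely.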

Results

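Single cells of early mouse embryos were profiled by RNA sequencing to compare embryos lacking Stat3 with wild-type embryos. STAT3 is the transcription factor that acts downstream of LIF and related cytokines and sustains naive pluripotency. The series title names metabolism and imprinted genes, so genes of both kinds were among the groups compared. At embryonic day (E) 3.5, 55 cells of the inner cell mass (ICM) came from 5 Stat3-null (MUT) embryos and 64 from 5 wild-type (WT) embryos. At E3.75, cells carried the label epiblast (EPI), the lineage that forms the fetus, or primitive endoderm (PrE), the lineage that forms the yolk sac endoderm. MUT embryos gave 9 EPI and 14 PrE cells from 4 embryos, and WT embryos gave 19 EPI and 10 PrE cells from 3 embryos. The titles of these 52 cells give E3.75 whereas their source label gives E3.5, and the titles are used here.

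Total counts per cell ran from 163822 to 25095390 over all 171 cells. The median was 3404703 in MUT and 5064704.5 in WT ICM cells, 10407966 and 11050855 in EPI, and 11168799 and 11123514 in PrE. A median of 9250 genes was detected in MUT and 8707 in WT ICM cells, 11114 and 11636 in EPI, and 10953 and 11264 in PrE. Counts were summed per embryo and lineage, which gave 24 sums from 17 embryos, and the embryo is the replicate in the tests of sums; values that take single cells as units are named as such. The MUT EPI of embryo 2 and the WT PrE of embryo 3 are each a single cell. By Y-linked and Xist reads, the E3.5 embryos were 1 male and 4 female among MUT and 3 male and 2 female among WT. All 4 MUT embryos at E3.75 were male, whereas 1 of the 3 WT embryos was male, so genotype and sex largely coincide there.

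Stat3 itself (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540, mm10) was strongly reduced in the cells labelled Stat3-null. In the ICM it stood at 5.66 ± 5.03 CPM (TMM-scaled; SD, n = 5 embryos) in MUT and 64.4 ± 23.9 (n = 5) in WT (exact two-sided permutation test over 252 splits, p = 0.00794). In EPI it stood at 9.60 ± 13.5 (n = 4) and 147 ± 47.1 (n = 3), and in PrE at 13.4 ± 6.03 (n = 4) and 97.5 ± 62.7 (n = 3), both with an exact permutation p = 0.0286, the smallest that 35 splits allow. The highest MUT embryo lay below the lowest WT embryo in each lineage, at 11.1 against 40.5 CPM in the ICM, 28.8 against 92.9 in EPI and 22.4 against 26.4 in PrE. No Stat3 count was found in 10 of 55 MUT and 1 of 64 WT ICM cells, 3 of 9 MUT EPI and 2 of 14 MUT PrE cells. Some MUT cells held more: 7 of 55 ICM cells, all of embryos 10 and 18, stood over 20 CPM of their own total. They reached 79.4, against a WT median of 61.0, but that value rests on 13 Stat3 counts among 163822. That cell, of embryo 18, is the shallowest of all cells. It held 73.3 CPM of Y-linked genes and 36.6 of Xist, although its embryo was called female. The next highest cell, of embryo 10, stood at 64.5 CPM with 108 Stat3 counts. MUT EPI and PrE cells reached 38.9 and 48.3. The genome-wide edgeR test gave log2 fold changes of −3.50 (SE 0.93), −3.93 (SE 1.59) and −2.86 (SE 0.64), with adjusted p values of 0.684, 0.972 and 0.737 that did not pass 0.05.

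**Figure D1:**
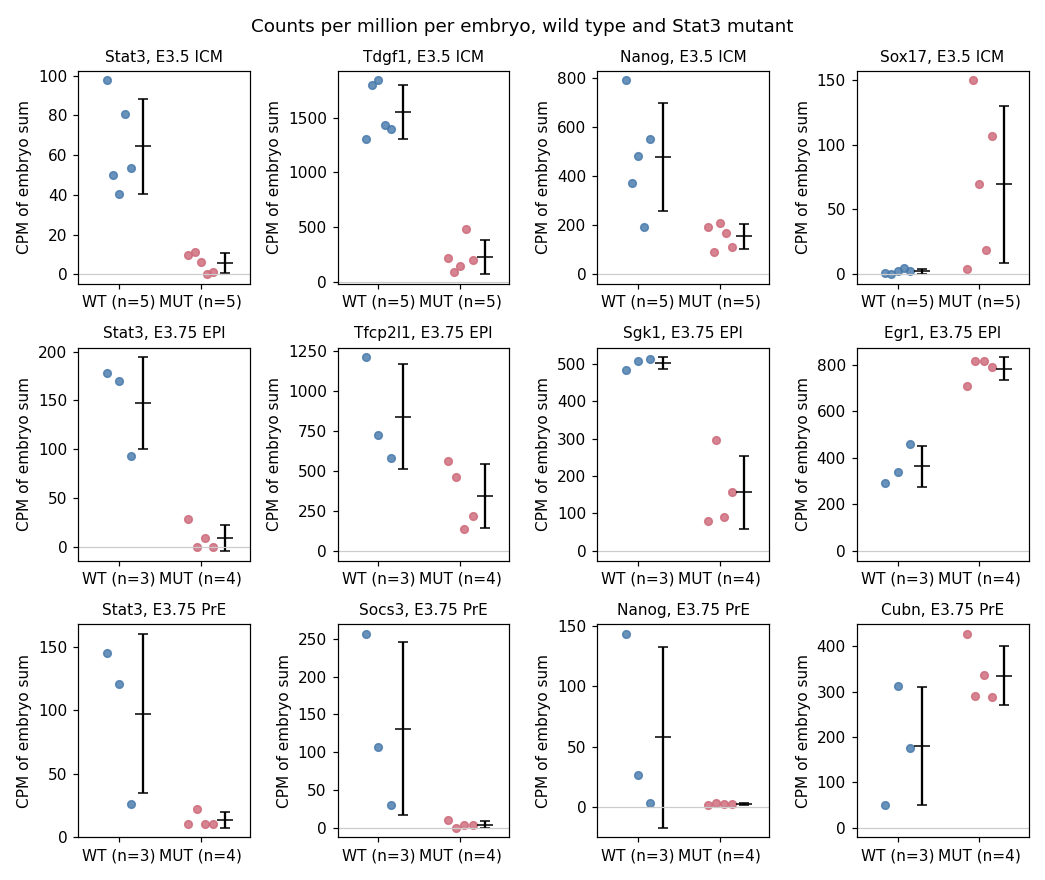
TMM-scaled CPM (y axis) of 4 genes in each of ICM, EPI and PrE; each point is an embryo, and the bar is the mean with its SD. Stat3 averages 5.66 CPM in MUT and 64.4 in WT ICM, and Tdgf1 223 against 1554.

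The E3.5 comparison asks what loss of Stat3 changes in the ICM before the lineages are labelled apart. At camera's preset correlation, markers of naive pluripotency and epiblast were lower as a group in MUT ICM, and markers of primitive endoderm were higher. Neither passed with an estimated correlation (adjusted p = 0.140 and 0.874). Tdgf1, the Nodal co-receptor Cripto (chromosome 9, 110939603 to 110946158), averaged 223 ± 154 CPM in MUT and 1554 ± 247 in WT (n = 5 each; log2 fold change −2.80, SE 0.44, edgeR adjusted p = 0.0839), with every MUT embryo below every WT embryo. Nanog, a core factor of the naive state (chromosome 6, 122707489 to 122714633), averaged 154 ± 52.5 and 478 ± 221 CPM (log2 −1.64, SE 0.42, adjusted p = 0.594). Sox17, a transcription factor of primitive endoderm (chromosome 1, 4490931 to 4497354), averaged 69.5 ± 60.5 CPM in MUT and 2.47 ± 1.84 in WT (log2 4.81, SE 1.04, adjusted p = 0.435).

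Of 24 naive and EPI markers measured in the ICM, 18 were lower and 6 higher, with a median log2 fold change of −0.70 (limma's camera, adjusted p = 3.85e-04 at the preset correlation, and adjusted p = 0.140 with an estimated correlation). The median was −0.43 without MUT 10 and −0.46 without WT 22, with the call kept. Limma's fry test called this list (adjusted p = 0.0259), but not the other 3 lists that camera called in the ICM (0.742 for PrE markers, 0.121 for TCA genes and 0.459 for imprinted genes). Tdgf1 and Nanog passed when adjusted over the list alone, and 0 members passed over all genes tested. Among 22 PrE markers 15 were higher (median 0.76, adjusted p = 0.0367, and 0.874 with an estimated correlation). Sox17 alone passed adjusted over the list alone, and Lamb1, a basement membrane laminin, averaged 677 ± 571 against 226 ± 114 CPM. The PrE call was lost in 5 of the 10 fits that left out an embryo: MUT 10 (median 0.13, adjusted p = 0.461), MUT 18 (0.0515), MUT 24 (0.133), WT 13 (0.0503) or WT 16 (0.267). It was also lost with embryo sex in the model (median 0.27, adjusted p = 0.814, the upper end of a range from 5.37e-04 over the alternatives) and under limma-trend (0.0606). Sex differs between the genotypes here.

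Genes of the tricarboxylic acid (TCA) cycle and α-ketoglutarate metabolism were lower as a group in MUT ICM, 18 of 24 (median −0.34, adjusted p = 0.0238, and 0.284 with an estimated correlation). Sucla2, a subunit of succinyl-CoA ligase, averaged 309 ± 18.9 CPM in MUT and 690 ± 272 in WT, and Got1, the cytosolic aspartate aminotransferase, 98.3 ± 29.9 and 214 ± 11.8. This call was lost without MUT 24 (adjusted p = 0.0539) or WT 13 (0.0883). Mitochondrial mRNA made up 3.15 ± 0.972% of counts in MUT and 4.86 ± 0.921% in WT ICM (mean of embryo medians, n = 5 each, exact permutation p = 0.0397). The 13 mitochondrially encoded mRNAs had a median of −0.25 (adjusted p = 0.0966), and mt-Cytb averaged 5307 ± 2494 against 11496 ± 4726 CPM. The 75 nuclear subunits of oxidative phosphorylation (OXPHOS) had a median of −0.04 (adjusted p = 0.579), and the 19 glycolytic genes −0.26 (adjusted p = 0.689). The mitochondrial mRNA and OXPHOS lists depend on the model. Limma-voom on single cells used the letter and, in the fit of genes, the embryo as a block. It gave medians of −1.35 for the mitochondrial mRNAs (camera adjusted p = 8.60e-13, in a range up to 0.801 over the alternatives) and −1.11 for OXPHOS subunits (2.22e-28, up to 0.905). Camera had no block here and took cells as replicates, so these p values overstate the evidence. Limma-trend gave −0.21 (0.00733) and 0.04 (0.272). Both lists passed as lower without MUT 2 (−0.42, 0.0201, and −0.24, 0.0172) or MUT 23 (−0.48, 0.0131, and −0.12, 0.0166). Without MUT 10 the mitochondrial median was −0.007 (0.801), and the OXPHOS list passed as higher (0.28, 0.00167).

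Imprinted genes, which are expressed from a single parental allele, were higher as a group in MUT ICM: 30 of the 39 measured, out of 81 listed (median 0.48, adjusted p = 0.0352, and 0.334 with an estimated correlation). None passed over all genes tested or adjusted over the list alone. The members with the smallest p went opposite ways: Gnas, which encodes the stimulatory G-protein α subunit, averaged 16.5 ± 14.4 CPM in MUT and 3.59 ± 1.44 in WT, and Grb10, a growth-restraining adaptor, 3.08 ± 3.41 and 15.1 ± 7.48. The call ended in 6 of the 10 fits without an embryo, namely MUT 10 (adjusted p = 0.0797), MUT 18 (0.0515), MUT 24 (0.137), WT 13 (0.0503), WT 16 (0.0826) and WT 22 (0.101). With embryo sex in the model the median was 0.23 and the adjusted p 0.266, the upper end of a range from 0.0137 over the alternatives. Regulators of DNA methylation did not move as a group (14 genes, median 0.08, mean 0.03, camera direction lower, adjusted p = 0.689), with Tet1, an oxidase of 5-methylcytosine, at 217 ± 78.6 against 445 ± 33.5 CPM and the de novo methyltransferase gene Dnmt3b at 107 ± 67.6 against 43.9 ± 7.31.

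STAT3 targets had a median of −0.78 in the ICM, with 13 of 17 lower, and did not pass as a group (adjusted p = 0.0795, and 0.855 with an estimated correlation; 0.00758 under limma-trend and 0.801 with embryo sex in the model, the ends of the range over the alternatives). They passed without MUT 23 (0.0462) or WT 21 (0.0109). Icam1, an adhesion molecule induced by cytokines, averaged 9.31 ± 10.1 CPM in MUT and 82.5 ± 67.0 in WT, and the kinase gene Sgk1 59.3 ± 37.8 and 201 ± 143. Formative and primed markers (8 genes, median 0.25), trophectoderm markers (9, 0.20), p53 targets (12, 0.13, mean −0.10), targets of FGF/ERK signalling (12, 0.07) and immediate early and heat shock genes (10, 0.09) had adjusted p values of 0.791, 0.881, 0.925, 0.458 and 0.891. Each of these 5 medians changed sign in at least 1 fit without an embryo.

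Gene by gene, edgeR called 0 of 12270 genes in the ICM, with 815 at an unadjusted p under 0.05. DESeq2 called 108 (74 higher), limma-trend on embryo means of log2(CPM + 1) called 2, and a limma-voom fit to single cells with the embryo as a random block called 1529 (777 higher). Without MUT 23, edgeR called 1 gene, Tdgf1 (adjusted p = 0.00911).

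**Figure D2:**
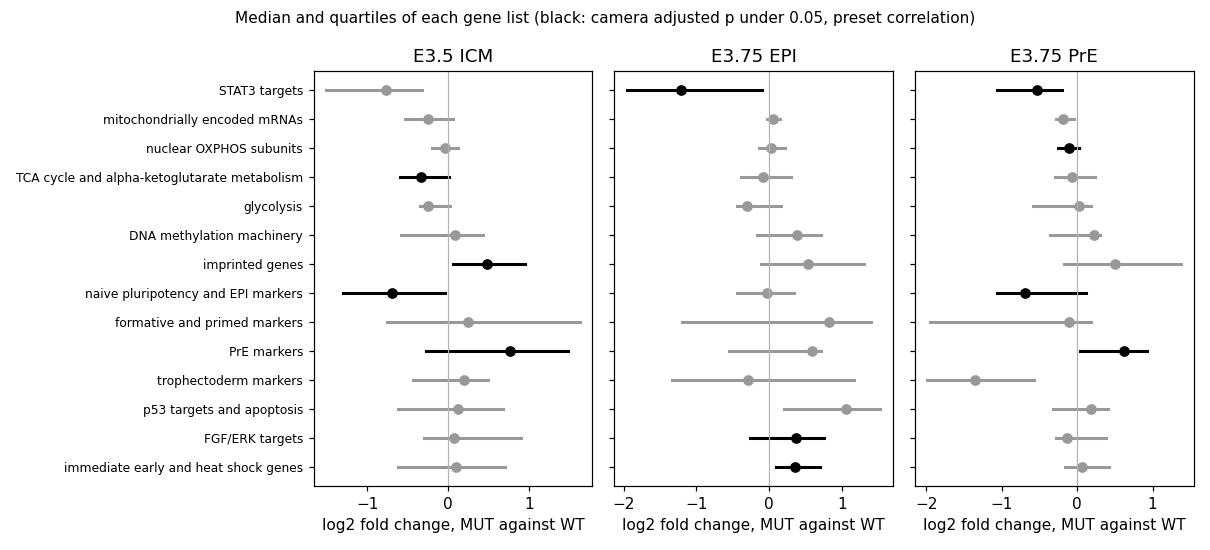
Median log2 fold change of MUT over WT (x axis) of 14 gene lists (y axis) in ICM, EPI and PrE; bars span the quartiles of the members, and black marks lists with a camera adjusted p under 0.05 at the preset correlation. The STAT3 targets have medians of −0.78, −1.22 and −0.53.

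The E3.75 EPI comparison asks what loss of Stat3 changes once the epiblast is labelled apart. At the preset correlation, known targets of STAT3 were lower as a group in MUT EPI, and genes induced by FGF/ERK signalling were higher. Neither passed with an estimated correlation (adjusted p = 0.0914 and 0.184), and the FGF/ERK call was lost in 7 of 15 alternatives. Sgk1, a serum- and glucocorticoid-induced kinase (chromosome 10, 21882184 to 21999903), averaged 156 ± 98.5 CPM in MUT (n = 4) and 501 ± 16.1 in WT (n = 3; log2 −1.68, SE 0.43, edgeR adjusted p = 0.339). Egr1, an immediate early transcription factor (chromosome 18, 34859823 to 34864984), averaged 782 ± 49.6 and 364 ± 87.3 CPM (log2 1.10, SE 0.19, adjusted p = 0.325), and every MUT embryo lay above every WT embryo.

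Of 18 STAT3 targets in EPI, 14 were lower (median −1.22, camera adjusted p = 3.05e-06, and 0.0914 with an estimated correlation), and the median was −0.61 without WT 1. Limma's fry test gave this list an adjusted p of 0.0292 and called no other in EPI (0.296 for FGF/ERK targets and for immediate early genes). Sgk1 passed adjusted over the list alone, and 0 passed over all genes tested. Klf4, Klf5, Tfcp2l1 and Gbx2 also stand in the list of naive and EPI markers, of which 13 of 25 were lower in EPI (median −0.03, mean above zero, camera direction lower, adjusted p = 0.813). Tfcp2l1, a naive-state transcription factor, averaged 345 ± 200 CPM in MUT and 839 ± 330 in WT.

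Targets of FGF/ERK signalling had a median of 0.37 (7 of 12 higher, adjusted p = 0.0301, and 0.184 with an estimated correlation). Egr1 alone passed adjusted over the list alone, and Etv4, an ETS factor, averaged 52.6 ± 43.2 against 6.60 ± 2.24 CPM. This call was lost without MUT 4 (adjusted p = 0.0720), MUT 5 (median 0.18, 0.0652) or WT 1 (0.08, 0.0546), and the median was 0.13 without MUT 2. It was also lost with embryo sex (0.0901), the title letter (0.0724) or the embryo number (0.154) in the model or under limma-trend (0.117), so it held in 8 of 15 alternatives. Among WT embryos, the fits with sex or the letter take genotype from WT 3 alone. The fit with the embryo number takes it from numbers 1 and 2 alone, which join MUT and WT embryos of no stated relation. Immediate early and heat shock genes, which share Egr1 and Ier2 with that list, had a median of 0.35 (8 of 10 higher, adjusted p = 0.0450, and 0.184 with an estimated correlation). Their call held in 1 of the 7 fits without an embryo, that without WT 1, and the adjusted p was 0.0653 without MUT 1, 0.113 without MUT 2, 0.05005 without MUT 4, 0.0652 without MUT 5, 0.103 without WT 2 and 0.216 without WT 3. It was also lost with the letter (0.0724) or the embryo number (0.178) and under limma-trend (0.0945), and held with embryo sex (0.00421).

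Imprinted genes in EPI had a median of 0.53, with 25 of 39 higher, and did not pass as a group (adjusted p = 0.0992, and 0.247 with an estimated correlation), and 0 members passed over all genes tested or adjusted over the list alone. Snrpn, a paternally expressed splicing component, averaged 276 ± 107 CPM in MUT and 107 ± 21.1 in WT (log2 1.37, SE 0.37, adjusted p = 0.341). Commd1 averaged 186 ± 33.6 and 131 ± 11.6. With embryo sex in the model the group passed (median 0.57, adjusted p = 0.0460), at the lower end of a range up to 0.644 over the alternatives. Without a call, the median was −0.06 under limma-trend, −0.14 with the embryo number as a block, 0.15 with the letter, 0.12 without MUT 2 (a single cell) and 0.29 without MUT 4.

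Metabolic genes did not pass as groups in EPI. The medians were −0.09 for 24 TCA genes (adjusted p = 0.813), −0.31 for 19 glycolytic genes (0.483), 0.03 for 75 OXPHOS subunits (0.0992) and 0.06 for 12 mitochondrially encoded mRNAs (0.292), and each changed sign in at least 1 fit without an embryo. OXPHOS subunits passed as higher without WT 1 (0.03, 0.0333) and with RLE scaling (0.07, 0.0445). With embryo sex in the model, mitochondrial mRNAs (median 0.29), OXPHOS subunits (0.06) and p53 targets (1.85) passed as higher, each at an adjusted p of 0.0108, and so did DNA methylation genes (0.56, 0.0384). Over the alternatives these 4 lists ranged up to 0.961, 0.717, 0.994 and 0.285. Idh3g, an X-linked subunit of isocitrate dehydrogenase, averaged 258 ± 35.2 CPM in MUT and 499 ± 87.9 in WT and was the 1 TCA gene that passed adjusted over the list alone. Slc2a3, a glucose transporter, averaged 62.3 ± 25.9 and 196 ± 105. The 14 regulators of DNA methylation had a median of 0.38 (adjusted p = 0.0605) and passed without WT 1 (0.0251), with RLE scaling (0.0475) and without a low-count filter (0.0170). Dnmt3a, which also stands among the formative markers, averaged 159 ± 169 against 7.75 ± 5.17 CPM and passed adjusted over that list alone. Formative and primed markers had a median of 0.82 (adjusted p = 0.0992), PrE markers 0.59 (0.307), p53 targets 1.06 (0.0992) and trophectoderm markers −0.29 (0.813), where Gata2 passed adjusted over the list alone at 0.0161 against 9.46 CPM. Formative markers passed without MUT 1 (0.0186), WT 2 (0.0362) or WT 3 (0.00274) and, like p53 targets (0.0457), without a low-count filter (0.00918). The p53 median was −0.15 without MUT 2, and the trophectoderm median ran from −1.48 without MUT 1 to −0.10 without WT 1 and was 0.18 with embryo sex. Over all genes edgeR called 0 of 12298, with 570 at an unadjusted p under 0.05 (181 higher, 389 lower), DESeq2 called 187 (51 higher) and limma-trend 0, which in simulated EPI counts recovered 0 of 100 genes changed by 4-fold and 28 by 32-fold.

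The PrE comparison asks the same of the sister lineage. At the preset correlation, STAT3 targets and naive markers were lower as groups in MUT PrE, and PrE markers were higher. None passed with an estimated correlation (adjusted p = 0.979 for each), and all were lost with embryo sex or the title letter in the model or without WT 1. Socs3, the feedback inhibitor of STAT3 signalling (chromosome 11, 117966079 to 117970047), averaged 4.08 ± 4.20 CPM in MUT (n = 4) and 131 ± 115 in WT (n = 3; log2 −5.01, SE 1.45, edgeR adjusted p = 0.940), with every MUT embryo below every WT embryo. Nanog averaged 2.65 ± 0.597 against 57.9 ± 74.97 CPM. Cubn, an endocytic receptor of the visceral endoderm, averaged 336 ± 64.6 against 180 ± 131, and its partner Lrp2 69.8 ± 49.2 against 8.02 ± 11.04.

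In PrE, 15 of 18 STAT3 targets were lower (median −0.53, adjusted p = 0.00436), 18 of 25 naive and EPI markers were lower (median −0.69, adjusted p = 0.00370) and 18 of 23 PrE markers were higher (median 0.62, adjusted p = 0.00370). Nuclear OXPHOS subunits were lower in 54 of 75 cases (median −0.10, adjusted p = 0.0157), with Ndufb6, a complex I subunit, at 258 ± 33.1 against 396 ± 50.3 CPM. With an estimated correlation all these lists had an adjusted p of 0.979, fry called none (adjusted p from 0.873 to 0.883), and 0 members passed over all genes tested or adjusted over a list alone. Without WT 1 all were lost (STAT3 targets, naive markers and OXPHOS subunits adjusted p = 0.249, PrE markers 0.590; medians −0.33 for STAT3 targets, −0.26 for naive and 0.31 for PrE markers). The PrE median was 0.23 without MUT 2. The naive call was also lost without MUT 2 (0.0712) and the OXPHOS call without MUT 1 (0.120) or WT 3 (0.5997), under limma-trend (0.460), and with the letter (0.0643) or the embryo number (0.766) in the model. With embryo sex in the model the STAT3 targets had a median of −0.03 (adjusted p = 0.965, from 8.80e-05 over the alternatives), naive markers 0.31 and PrE markers 0.37 (both 0.978, from 1.30e-05). With the letter these medians were −0.06, 0.65 and 0.16 (all adjusted p = 0.917). The only male WT sum in PrE is a single cell. The fit with the embryo number takes genotype from numbers 1 and 2 alone.

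Imprinted genes in PrE had a median of 0.51, with 26 of 40 higher (mean 0.29, adjusted p = 0.607, and 0.979 with an estimated correlation), and 0 passed over all genes tested or adjusted over the list alone. Without a call, the median was 3.45 with embryo sex, 2.65 with the letter, 0.09 with the embryo number as a block and 0.11 under limma-trend, and it ran from 0.24 without MUT 2 to 0.93 without WT 2. Pon2, a paraoxonase gene, averaged 0.0310 against 42.6 ± 49.8 CPM, and Xist, the X-inactivation RNA that female embryos express, 0.633 against 303 ± 266. Trophectoderm markers had a median of −1.36, with 9 of 10 lower (adjusted p = 0.214). This direction is not stable: the median was 1.16 without WT 1, 2.82 with embryo sex, 0.60 with the letter and 0.27 with the embryo number, and the list passed as lower without WT 2 (−1.92, 0.0158) and without a low-count filter (0.00353). Mitochondrial mRNAs passed as lower without MUT 1 (0.00343) and with the letter (0.00333). The remaining 8 lists had adjusted p values from 0.214 to 0.957. Over all genes edgeR called 0 of 11765, with 545 at an unadjusted p under 0.05, DESeq2 called 157 (84 higher) and limma-trend 0. With embryo sex as a covariate edgeR called 217, of which 200 were higher. In PrE the fits with sex or the letter take genotype from 1 WT sum, which is a single cell. Their values, here and for the imprinted genes, cannot separate genotype from that cell.

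The share of E3.75 cells labelled EPI was lower in MUT embryos. It averaged 39.6 ± 7.22% (SD, n = 4) in MUT and 67.3 ± 17.5% (n = 3) in WT embryos, a difference of −27.7 points (exact two-sided permutation test, p = 0.0286, the smallest of 35 splits). The MUT embryos stood at 50.0 (2 of 4 cells), 33.3 (1 of 3), 37.5 and 37.5% (3 of 8 each). The WT embryos stood at 57.1 (4 of 7), 57.1 (8 of 14) and 87.5% (7 of 8). Genotype and sex largely coincide in these embryos. Pooled over embryos, 9 of 23 MUT cells (39.1%, 95% Clopper-Pearson interval 19.7 to 61.5%) and 19 of 29 WT cells (65.5%, 45.7 to 82.1%) carried the EPI label, and these intervals overlap. The labels do not say how cells were assigned or chosen for sequencing, so the shares describe the cells sequenced. Leaving out any 1 embryo gave differences from −32.7 to −17.6 points with exact p values from 0.0667 to 0.100, since fewer embryos cannot give less.

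The comparison of EPI with PrE in the same embryos asks how the lineages differ and whether the difference holds without Stat3. How the cells received their lineage label is not given in the sources used here, so known markers may be part of the definition. In WT, edgeR on unpaired sums called 4 genes, and each lost its call with the embryo as a block (adjusted p = 0.170 for each) and without any 1 of the 3 embryos (0.0687 to 0.595). Fgf4, the ligand that epiblast cells send to the endoderm (chromosome 7, 144847367 to 144865243), averaged 141 ± 31.98 CPM in EPI and 0.704 ± 0.321 in PrE (n = 3 each; log2 7.59, SE 0.54, edgeR adjusted p = 0.0223). Sox17 averaged 10.7 ± 1.65 against 475 ± 118 CPM (log2 −5.47, SE 0.30, adjusted p = 0.0119), Dkk1, a secreted Wnt antagonist, 0.430 ± 0.0617 against 150 ± 91.4 (log2 −8.43, SE 0.69, adjusted p = 0.0337), and Mgst3, a microsomal glutathione transferase, 26.4 ± 3.56 against 233 ± 24.7 (log2 −3.14, SE 0.24, adjusted p = 0.0223). In MUT, Fgf4 rose in EPI to 129 ± 34.8 from 0.413 ± 0.209 CPM (n = 4 each; log2 8.31, SE 0.58, adjusted p = 1.62e-04) and Nanog to 589 ± 353 from 2.71 ± 0.644 (log2 7.76, SE 0.55, adjusted p = 1.85e-04), and both passed with the block (0.00474 and 0.00735).

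In MUT, the laminin gene Lama1 fell to 4.01 ± 1.88 CPM in EPI from 650 ± 165 in PrE (log2 −7.36, SE 0.44, adjusted p = 7.36e-05), and the endoderm factor Gata4 to 2.50 ± 2.62 from 348 ± 65.1 (adjusted p = 0.00172). Otx2, a factor of the later epiblast, rose to 79.6 ± 62.7 from 0.234 ± 0.112 (adjusted p = 0.00234), and Eras, a Ras family gene of embryonic stem cells, to 55.9 ± 14.8 from 0.131 ± 0.0750 (adjusted p = 0.00105). Others among the largest rises were Lpl, Igfbp2, Rnf213 and Zic5, and among the largest falls Ticam1, Efnb1, Dhrs7, Bmp6 and Aldh1a1. Of the genes in this paragraph, Lama1, Gata4, Otx2 and Eras passed in 4 of 4 fits that left out an embryo and with the embryo as a block (adjusted p = 0.00187, 0.0200, 0.0198 and 0.0248). With the block Igfbp2 (0.0308) and Rnf213 (0.0191) also passed, and Lpl (0.0507), Zic5 (0.137), Ticam1 (0.114), Efnb1 (0.144), Dhrs7 (0.118), Bmp6 (0.162) and Aldh1a1 (0.0531) did not.

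As groups, 23 of 25 naive and EPI markers were higher in MUT EPI than in MUT PrE (median 2.20, adjusted p = 9.91e-21), and 7 passed over all genes tested and 11 adjusted over the list alone. All 23 PrE markers were lower (median −4.77, adjusted p = 6.71e-54), with 15 past the threshold over all genes tested and 19 adjusted over the list alone. Of all the camera calls in the 9 comparisons, these were the only ones that held with an estimated correlation (adjusted p = 0.00863 and 1.16e-04). In WT the same markers had medians of 1.17 (21 of 25 higher, adjusted p = 3.76e-09, and 0.289 with an estimated correlation) and −4.46 (20 of 22 lower, adjusted p = 3.48e-28, and 0.157). Fry called these lists in MUT and none in WT (0.0584 for both). Over all genes 1 member of each passed in WT, Fgf4 and Sox17, and adjusted over the list alone 6 naive markers passed as higher and 1 as lower, and 18 PrE markers as lower.

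Glycolytic genes were lower in EPI than in PrE of MUT embryos, 14 of 19 (median −0.26, adjusted p = 0.0191, and 0.422 with an estimated correlation), with 2 members past the threshold over all genes and adjusted over the list alone. Pfkl, a phosphofructokinase, fell to 67.9 ± 21.4 from 529 ± 158 CPM (log2 −2.96, SE 0.32, adjusted p = 0.00217), and Slc2a3 to 61.2 ± 25.4 from 776 ± 377 (log2 −3.66, SE 0.46, adjusted p = 0.00443); both passed with the block (0.0302 and 0.0308). The list call was lost without MUT 2 (median −0.13, adjusted p = 0.206) and under limma-trend (0.166), and the median was −0.46 without MUT 1 and −0.57 without MUT 4. In WT the list had a median of −0.31 (adjusted p = 0.0600) and passed with the embryo as a block (adjusted p = 0.00451, within a range over the alternatives of up to 0.333). OXPHOS subunits (median −0.09, 50 of 75 lower, adjusted p = 0.0276), TCA genes (median −0.18, 18 of 24 lower, 0.0475) and trophectoderm markers (median −3.06, 11 of 12 lower, 0.0174) were lower as groups in WT EPI, with adjusted p = 0.716, 0.289 and 0.716 with an estimated correlation. The trophectoderm median was −1.05 with the embryo as a block, −0.85 under limma-trend and −1.11 without WT 1, and the OXPHOS median −0.05 without WT 1. Without WT 1 these calls ended (adjusted p = 0.0914, 0.0914 and 0.414), as did OXPHOS and TCA without WT 3 (0.682 and 0.333) and under limma-trend (0.338 and 0.244). In MUT the block added calls of lower TCA genes and trophectoderm markers (both adjusted p = 0.0432), which without it were 0.0554 and 0.138.

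Among imprinted genes, Cobl, an actin nucleator, rose in MUT EPI to 277 ± 176 from 2.03 ± 2.05 CPM (log2 7.07, SE 0.84, adjusted p = 0.00296), and Igf2, a fetal growth factor, averaged 0.0659 against 14.5 ± 9.18 (adjusted p = 0.0363). In WT, Cobl averaged 121 ± 93.1 against 0.661 ± 0.152 CPM (adjusted p = 0.125). Trim28, a co-repressor that protects imprints, averaged 595 ± 266 in MUT EPI and 165 ± 61.3 in MUT PrE (adjusted p = 0.0407), and Pramel7, a STAT3 target, 4.89 ± 5.19 and 162 ± 98.3 (adjusted p = 0.0363). With the embryo as a block Cobl passed (0.0393), and Igf2 (0.134), Trim28 (0.173) and Pramel7 (0.0662) did not, nor in any fit without an embryo; Cobl failed without MUT 1 (0.0502). Imprinted genes as a group had medians of 0.12 in WT (adjusted p = 0.657; 0.05 to 0.46 without an embryo, 0.81 with the block) and −0.06 in MUT (mean 0.15, camera direction higher, adjusted p = 0.488; −0.19 to 0.40).

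**Figure D3:**
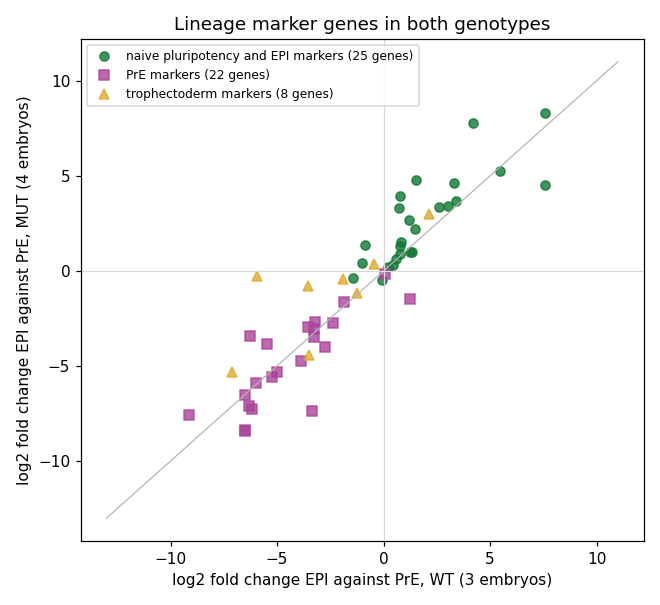
Log2 fold change of EPI over PrE in WT (x axis, 3 embryos) and MUT (y axis, 4 embryos) for markers of 3 lineages; each point is a gene. The PrE markers have medians of −4.46 in WT and −4.77 in MUT, and the naive and EPI markers 1.17 and 2.20.

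Over all genes, edgeR called 4 of 12733 genes between EPI and PrE in WT (1 higher) and 177 of 10698 in MUT (54 higher, 123 lower), with 1190 and 1090 at an unadjusted p under 0.05. DESeq2 called 727 (367 higher) and 631 (271 higher). With the embryo as a block, edgeR called 0 in WT and 74 in MUT. Each fit without a WT embryo (1, 2 or 3) called 0, and MUT counts were 71 without embryo 1, 91 without 2, 77 without 4 and 74 without 5. Of the 177 genes called in MUT, 166 were tested in WT, where 164 had the same direction, 104 of them at an unadjusted p under 0.05 and 3 called.

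The test of the difference itself asked whether loss of Stat3 acted unequally on EPI and PrE. edgeR called 0 of 14220 genes, with 783 at an unadjusted p under 0.05, DESeq2 called 333 and limma-trend 0. The smallest adjusted p was that of Gdpd5, a glycerophosphodiesterase gene (log2 difference −5.40, SE 0.85, adjusted p = 0.287), and Dppa2, a gene of pluripotent cells, had 1.66 (SE 0.35, adjusted p = 0.719). Naive and EPI markers (median difference 0.68, 17 of 25 higher, adjusted p = 0.00169), OXPHOS subunits (0.11, 48 of 75 higher, 0.00299) and formative markers (0.98, 7 of 11 higher, 0.0360) passed as groups at the preset correlation, with adjusted p = 0.431, 0.431 and 0.445 with an estimated correlation. Fry called none (0.674 for each). These calls ended without MUT 2 for naive markers (adjusted p = 0.0593), without MUT 1 (0.0552) or WT 3 (0.141) for OXPHOS subunits, and without MUT 2 (0.0593), MUT 4 (0.177) or WT 2 (0.0761) for formative markers. The naive median was 0.35 without WT 1 and 0.41 with the embryo as a block, the OXPHOS median 0.016 without MUT 1 and 0.026 without WT 1, and the formative median 0.52 without MUT 4. Limma-trend ended all 3 (naive 0.181, OXPHOS 0.248, formative 0.181). The formative call also ended without genes on X and Y (0.0561). Imprinted genes had a median difference of −0.35 (adjusted p = 0.718; −0.84 to 0.31 without an embryo), and STAT3 targets −0.36 (adjusted p = 0.638).

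The comparison of E3.75 EPI with E3.5 ICM asks what changes as the epiblast forms. Stage coincides with the letter in the sample titles and goes with depth per cell, so these cannot be told apart. In MUT stage also nearly coincides with sex, since all 4 EPI embryos were male and 4 of 5 ICM embryos female, and no fit with sex was run for the stages. In WT, the biosynthetic enzyme gene Srm (spermidine synthase, chromosome 4, 148591503 to 148594993) rose in EPI to 309 ± 21.9 CPM (n = 3) from 17.8 ± 8.62 (n = 5; log2 4.12, SE 0.44, edgeR adjusted p = 0.0127), Egr1 to 318 ± 73.7 from 33.5 ± 15.5 (log2 3.24, SE 0.41, adjusted p = 0.0244) and Pim3, a kinase gene induced by STAT3, to 119 ± 17.5 from 3.63 ± 3.13 (log2 5.03, SE 0.78, adjusted p = 0.0429). Suclg1, a subunit of succinyl-CoA ligase, fell to 282 ± 45.4 from 769 ± 83.4 (log2 −1.45, SE 0.22, adjusted p = 0.0407), the constitutive chaperone gene Hspa8 to 1616 ± 135 from 3573 ± 273 (adjusted p = 0.0407) and the mitochondrial ribosomal RNA mt-Rnr1 to 619 ± 367 from 6431 ± 847 (adjusted p = 0.0127). Of the 8 fits without an embryo, mt-Rnr1 passed in 6, Srm in 5, Egr1 in 4, Suclg1 and Hspa8 in 2 and Pim3 in 1 (highest adjusted p 0.122, 0.108, 0.228, 0.278, 0.278 and 0.278).

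STAT3 targets were higher as a group in WT EPI than in WT ICM (13 of 19, median 1.42, adjusted p = 3.93e-04), and PrE markers (18 of 22, median −1.80, 3.00e-05) and TCA genes (18 of 24, median −0.44, 0.00270) were lower. All had an adjusted p of 0.234 with an estimated correlation. Over all genes tested 1 STAT3 target, Pim3, and 1 TCA gene, Suclg1, passed, and adjusted over the list alone 4 STAT3 targets passed as higher and 1 as lower, 7 TCA genes as lower and 2 PrE markers as lower. Targets of FGF/ERK signalling passed as higher (median 0.03, mean 0.52, 6 of 12 higher, adjusted p = 0.0238, and 0.262 with an estimated correlation), with Egr1 past the threshold over all genes and 2 members adjusted over the list alone; this call ended without WT 16 (0.0718) and under limma-trend (0.106), and the median ran from −0.19 without E3.5 WT 13 to 0.60 without E3.5 WT 22. The TCA call ended under limma-trend (adjusted p = 0.455, from 0.00168 over the alternatives). The STAT3 median was 0.82 without E3.75 WT 1. The other 10 lists had adjusted p values from 0.0608 to 0.792, and of these naive markers passed as higher in 7 and OXPHOS subunits as lower in 6 of 14 alternatives.

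In MUT, Igfbp2, a binding protein of insulin-like growth factors, rose in EPI to 49.5 ± 33.3 CPM (n = 4) from 0.0325 (n = 5), the claudin gene Cldn6 to 144 ± 59.6 from 1.93 (0 to 3.78 over embryos), Cobl to 255 ± 163 from 20.1 ± 11.9, Zfp36l1, an RNA-decay factor, to 331 ± 137 from 41.7 ± 12.2 and Itpk1, an inositol phosphate kinase, to 286 ± 53.9 from 36.2 ± 19.4, all with an edgeR adjusted p of 0.0478. Timd2 fell to 1.18 ± 0.373 from 250 ± 182 (log2 −7.73, SE 0.81, adjusted p = 0.00390) and passed in 8 of 9 fits without an embryo. Psmb9, an immunoproteasome subunit, fell to 0.0511 from 29.4 ± 20.2 (adjusted p = 0.0478). Xist had no counts in the 4 MUT EPI sums, all male, and 351 ± 308 CPM in the ICM, at least 11739-fold lower against a floor of 3 counts over the EPI group (adjusted p = 0.0478). Of the 9 fits without an embryo, Igfbp2 and Zfp36l1 passed in 2 and Cldn6, Cobl, Itpk1, Psmb9 and Xist in 1 (highest adjusted p from 0.137 to 0.222).

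As groups, naive and EPI markers (19 of 24, median 1.33, adjusted p = 1.93e-06), FGF/ERK targets (9 of 12, median 0.60, 0.00179), immediate early and heat shock genes (7 of 10, median 1.65, 0.00179), formative markers (6 of 8, median 0.84, 0.00890) and glycolytic genes (11 of 19, median 0.15, 0.0389) were higher in MUT EPI than in MUT ICM, and PrE markers were lower (22 of 23, median −2.11, 3.90e-07). With an estimated correlation the adjusted p values were, in that order, 0.0563, 0.0563, 0.0839, 0.144, 0.436 and 0.144. Over all genes tested 0 members of these lists passed, and adjusted over the list alone 8 naive markers passed as higher and 1 as lower, 3 FGF/ERK targets, 2 immediate early genes and 2 formative markers as higher, 0 glycolytic genes, and 7 PrE markers as lower. The formative call ended without the E3.75 embryo MUT 4 (adjusted p = 0.0572), and the glycolytic call without the E3.5 embryos MUT 2 (0.165) or 23 (0.0590) or the E3.75 embryos MUT 4 (0.283) or 5 (0.0876). Limma-trend ended the FGF/ERK (adjusted p = 0.0561), immediate early, formative and glycolytic calls (each 0.0891). The formative call also ended without genes on X and Y (0.0652). OXPHOS subunits (median −0.21, camera direction higher, adjusted p = 0.8501) passed as lower without E3.5 MUT 10 (−0.39, 2.66e-04). Egr1 averaged 707 ± 43.2 CPM in MUT EPI and 60.6 ± 49.8 in MUT ICM.

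Over all genes, edgeR called 43 of 13972 genes between the stages in WT (24 higher, 19 lower) and 8 of 11733 in MUT (5 higher, 3 lower), with 1966 and 948 at an unadjusted p under 0.05. The median log2 fold change of all genes in WT was −0.14. DESeq2 called 1069 (370 higher) and 414 (118 higher), and limma-trend 4048 (3974 higher, median of all genes 0.68) and 223 (210 higher, median 0.65). Counts without an embryo were, in WT, 162 without E3.5 embryo 13, 18 without 16, 7 without 20, 11 without 21, 70 without 22, and 3, 0 and 2 without E3.75 embryos 1, 2 and 3. In MUT they were 17 without E3.5 embryo 10, 1 without 18, 2 or 24, 3 without 23, 5 without E3.75 embryo 1, 0 without 2 and 1 without 4 or 5.

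Whether loss of Stat3 acted unequally on E3.75 EPI and E3.5 ICM was tested in the same way. edgeR called 0 of 15756 genes, with 1458 at an unadjusted p under 0.05, DESeq2 called 501 and limma-trend 0; the smallest adjusted p, 0.230, was shared by Tat, Habp4, Qsox2, Cbr2 and Rab31. At the preset correlation, STAT3 targets were further reduced in EPI as a group (median difference −0.72, 13 of 19 lower, adjusted p = 0.0275, and 0.448 with an estimated correlation), and naive markers had a median difference of 0.44 (17 of 25 higher, adjusted p = 0.0161, and 0.165 with an estimated correlation). Fry called no list (0.281 and 0.343 for these). Imprinted genes had a median difference of −0.29 (adjusted p = 0.351; −0.88 to −0.06 without an embryo). The STAT3 median ran from −0.32 without E3.75 WT 1 to −1.41 without E3.5 WT 13, and the naive median from 0.29 without E3.5 MUT 10 to 0.69 without E3.5 MUT 23. The STAT3 call ended in 9 of the 17 fits without an embryo: E3.5 MUT 10 (adjusted p = 0.0689), 18 (0.0632) and 23 (0.0653), E3.5 WT 20 (0.0579), 21 (0.107) and 22 (0.0582), E3.75 MUT 4 (0.107) and 5 (0.0744) and E3.75 WT 1 (0.135). The naive call ended without E3.5 MUT 10 (0.0689) or E3.5 WT 22 (0.0549) and under limma-trend (0.0995).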

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

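All tests of explanations and all counts of other splits in this part were chosen only after the results were seen; the covariate fits they draw on were planned.

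STAT3 targets were lower in MUT EPI (median −1.22) at the preset correlation but not at an estimated one (adjusted p = 0.0914). Of the 35 splits of the 7 embryos only the real one gave a camera p as small, 2.18e-07 against 9.44e-07 for the next. This share is unadjusted for the lists examined. FGF/ERK targets and the uncalled DNA methylation genes also had 1 of 35 in EPI, so chance is not excluded. Embryo sex and the title letter follow genotype in part. The list stayed past the threshold with sex as a covariate (median −0.73, adjusted p = 4.28e-04) and with the letter (median −1.48, adjusted p = 2.26e-05). These fits cannot exclude either cause, since both take genotype from 1 WT embryo. All MUT sums are male, and WT 3 is the only male WT sum and the only one sharing a letter with MUT sums. Over the alternatives the adjusted p ran from 4.04e-08 to 0.0151. The list passed in each fit without an embryo, although the median was −0.61 without WT 1. In PrE the real split also gave the smallest camera p (1 of 35, 9.34e-04 against 0.00100), but sex (median −0.03, adjusted p = 0.965) and the letter (−0.06, adjusted p = 0.917) cannot be told apart from genotype there (range over the alternatives 8.80e-05 to 0.965; 0.249 without WT 1), because the only male WT sum, which is also the only one sharing a letter with MUT sums, is a single cell. Loss of Stat3 may account for the lower targets in EPI, as a hypothesis found and tested on the same data. In both lineages it stays open beside sex, letter and chance.

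Naive and EPI markers were lower in MUT ICM (median −0.70) at the preset correlation but not at an estimated one (adjusted p = 0.140). Of 100 splits of the 10 embryos, 3 gave a camera p as small as the real 2.75e-05 (smallest other 2.21e-06). Another split thus gave a smaller p than the real one, and the share is unadjusted for the lists examined, so chance is not excluded. Embryo sex is argued against as the whole cause, since the list stayed past the threshold with sex as a covariate (median −0.76, adjusted p = 0.0332, the highest of a range from 1.70e-05 over the alternatives). The list also passed in each fit without an embryo, with medians of −0.43 without MUT 10 and −0.46 without WT 22. A larger share of cells turning to primitive endoderm among the MUT cells could lower the same markers and raise those of PrE, which were higher. The PrE list leaves it open: 33 of 100 splits gave a camera p as small as the real 0.0105 (smallest other 2.11e-08), and its call was lost without MUT 10 (0.461), MUT 18 (0.0515), MUT 24 (0.133), WT 13 (0.0503) or WT 16 (0.267) and with embryo sex as a covariate (median 0.27, adjusted p = 0.814), so it cannot be told apart. A lower level per cell with loss of Stat3 stays open as well.

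Other splits of the embryos bear on the counts as follows, each as splits with a result as large, the real one included. For the 177 genes between EPI and PrE in MUT, 1 of 35 splits gave as many (highest other 2), but these sums are paired by embryo, and the 8 splits that part all 4 embryos are too few for a share under 0.05 (highest other 0). For the 43 genes between the stages in WT, 1 of 56 splits gave as many (highest other 5), which argues against chance, unadjusted for the counts examined. For the 8 genes between the stages in MUT the share was 2 of 100. The highest other, 13, came from the split that puts E3.5 MUT embryo 10 with the EPI sums. For the 7 lists of the stage interaction it was 3 of 100 (highest other 8). In these last cases another split gave more than the real one, and the shares are unadjusted, so chance is not excluded. For WT EPI against PrE the 10 splits are too few for a share under 0.05 (4 genes in 1 split, highest other 0, also among the 4 splits that part all 3 embryos; 5 lists in 3 splits, highest other 6). Chance is not excluded for the list counts of the ICM (4 lists, 18 of 100, highest other 6), EPI (3, 11 of 35, 7) and PrE (4, 12 of 35, 6) comparisons, of EPI against PrE in MUT (3, 8 of 35, 4), of the stages in WT (4, 11 of 56, 6) and in MUT (6, 7 of 100, 8), or of the lineage interaction (3, 13 of 35, 6). The same holds for imprinted genes in the ICM (6 of 100 splits, p = 0.00753, smallest other 0.00149), EPI (7 of 35, 0.0567, 0.0113) and PrE (20 of 35, 0.304, 0.00101). The counts of 0 genes by edgeR are matched in any split (100 of 100 in the ICM, highest other 2; 35 of 35 in EPI and in PrE, highest other 1 in each; 35 of 35 and 100 of 100 in the lineage and stage interactions, highest other 2 in each). At an unadjusted p under 0.05 these 5 comparisons held 815, 570, 545, 783 and 1458 genes, and DESeq2 called 108, 187, 157, 333 and 501.

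The difference of the genotype effects between EPI and PrE passed for 3 gene lists at the preset correlation: naive and EPI markers (adjusted p = 0.00169), OXPHOS subunits (0.00299) and formative markers (0.0360). None passed with an estimated correlation (0.431, 0.431 and 0.445) or under limma-trend (0.181, 0.248 and 0.181). The naive call ended without MUT 2 (0.0593), the OXPHOS call without MUT 1 (0.0552) or WT 3 (0.141) and the formative call without MUT 2 (0.0593), MUT 4 (0.177) or WT 2 (0.0761). Between E3.75 EPI and E3.5 ICM the same test passed for STAT3 targets (0.0275, and 0.448 with an estimated correlation), naive markers (0.0161, and 0.165), mitochondrially encoded mRNAs (median difference 0.35, 0.0161, and 0.571), OXPHOS subunits (0.03, 0.0161, and 0.645), TCA genes (0.31, 0.0161, and 0.165), DNA methylation genes (0.34, 0.0164, and 0.165) and formative markers (0.76, 0.0356, and 0.448). The formative median ran from −0.31 without E3.75 MUT 4 to 1.5997 without E3.75 WT 3, the OXPHOS median from −0.22 without E3.5 MUT 10 to 0.20 without E3.5 MUT 2, and the mitochondrial median was 0.056 without E3.75 MUT 2 and 0.083 without E3.5 MUT 10, so the direction of formative and OXPHOS genes rests on single embryos. Limma-trend ended the calls of OXPHOS subunits (0.329) and of TCA, DNA methylation, naive and formative genes (each 0.0995). Leaving out E3.5 WT 22 ended the calls of TCA, DNA methylation and naive genes and of formative markers (all 0.0549), mitochondrial mRNAs (0.0549) and OXPHOS subunits (0.332), and leaving out E3.5 MUT 10 ended mitochondrial mRNAs (0.287), OXPHOS subunits (0.366), STAT3 targets, naive and formative markers (all 0.0689). STAT3 targets also failed without E3.5 MUT 18 (0.0632) or 23 (0.0653), E3.5 WT 20 (0.0579), 21 (0.107) or 22 (0.0582), E3.75 MUT 4 (0.107) or 5 (0.0744), or E3.75 WT 1 (0.135). Mitochondrial mRNAs also failed without E3.5 MUT 18 (0.0551), E3.75 MUT 2 (0.0546) or E3.75 WT 3 (0.0525), OXPHOS subunits without E3.5 MUT 18 (0.0632), and formative markers without E3.5 MUT 18 (0.0564), 2 (0.0920) or 23 (0.0503), E3.5 WT 20 (0.210) or 21 (0.0512), E3.75 MUT 4 (0.296) or 5 (0.119), or E3.75 WT 1 (0.112).

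Of 138 groups of 4 or 5 embryos examined for a value far from the rest, 19 held one, where chance gives about 1 in 20. That rate does not hold where the other embryos all held 0, since any count is then flagged. Such are Gata2 in MUT EPI and PrE, and Pon2 and Xist in MUT PrE. Stat3 in PrE stood at 22.4 CPM in MUT embryo 2, against 10.3 to 10.5 in the other MUT embryos. Dusp4 in MUT ICM stood at 1.76 CPM in embryo 2, against 55.3 to 73.1, and Pkm at 401 in the same embryo, against 709 to 809. Foxd3 stood at 26.0 CPM in MUT ICM embryo 23 and Zmat3 at 10.3 in WT ICM embryo 21. In MUT EPI, embryo 5 held 780 CPM of Ier2 (others 317 to 369), 5.80 of Foxa2 and 0.0645 of Gata2, and embryo 1 held 23.6 CPM of Slc2a3 (others 72.5 to 78.2). In MUT PrE, embryo 1 held 0.140 CPM of Lrp2 (others 78.5 to 116) and 3.07 of Cdkn1a, embryo 4 held 2.22 of Gata2 and 2.53 of Xist, and embryo 5 held 7.34 of Cdh2 and 0.124 of Pon2. Mitochondrial mRNA made up 5.29% of counts (median over cells) in PrE of MUT embryo 1. In ICM of WT embryo 13, nuclear coding genes held 67.2% and the 10 most abundant genes 32.6% of counts. The median total count of MUT EPI embryo 1 was 11201876.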

How the results depend on the processing

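The fits without genes on X and Y and without cells holding both Y-linked and Xist reads were chosen only after the data were seen. Of 3398 alternative values for named genes, 2980 kept their direction and side of the threshold, 235 lost and 157 gained a call, 26 moved and 0 reversed. Of 1882 for gene lists, 1552 kept both, 113 lost, 82 gained, 129 moved and 6 reversed. Of 205 for counts of genes, imprinted genes as a group and the EPI share, 136 stayed the same, 14 lost, 1 gained, 54 moved and 0 reversed. A count of genes stayed the same if it was equal or close in ratio. The EPI share counts as lost in each fit without an embryo, where its exact p cannot fall under 0.05. Directions of lists here are those of camera, not the sign of the median: PrE markers in PrE count as reversed at medians of 0.37 and 0.16 (0.62 without a covariate), whereas naive markers at 0.31 (from −0.69) and trophectoderm markers at 2.82 (from −1.36) in PrE with sex do not. Where no cause is named below, the cause was not tested. DESeq2 called 108 genes in the ICM, 187 in EPI and 157 in PrE. Between EPI and PrE it called 727 in WT and 631 in MUT, and between the stages 1069 and 414. In the lineage and stage interactions it called 333 and 501. On simulated data DESeq2 made more false calls than edgeR. Those data were drawn with edgeR's own dispersions, so they cannot decide which calls are right. Limma-trend called 2 in the ICM, 7 and 321 between the lineages, and 4048 and 223 between the stages. Without a low-count filter edgeR called 3 in the ICM, 32 between the lineages in WT, and 85 and 22 between the stages. Limma-voom on single ICM cells called 1529, and 1334 with the letter. In the ICM 1 gene was called without low-quality cells and 1 without cells holding both Y-linked and Xist reads, which also left 1 between the stages in MUT; leaving out sums of 1 cell left 0 there. RLE scaling, limma-trend and the fit without genes on X and Y each called 7 between the lineages in WT. The embryo as a replicate block gave 0 and 74 between the lineages in WT and MUT and changed no list call beyond those in the lineage results and that of mitochondrial mRNAs in the lineage interaction (adjusted p = 0.0224, against 0.0576 without it). For genotype, numbers 1 and 2 are shared by MUT and WT embryos, whose relation the labels do not give. Their mean correlation was 0.0612 in EPI (0.142 for number 1 and −0.0195 for number 2) and −0.00692 in PrE (2 pairs each). The replicate block on these numbers takes genotype from numbers 1 and 2 alone and gave 0 calls in EPI and 0 in PrE. Embryo sex as a covariate gave 217 in PrE, where the all-gene median moved to 0.46 and genotype then rests on a single WT cell. This covariate moved imprinted genes in the ICM to 0.23 (call lost) and in EPI to 0.57 (call gained). It turned PrE markers in PrE in camera's direction (median 0.37). The letter as a covariate turned naive markers in PrE to 0.65 (0.31 with sex) and, in camera's direction, PrE markers (median 0.16). Leaving out each embryo gave 0 to 1 genes in the ICM, 0 between the lineages in WT, 71 to 91 in MUT, 0 to 162 between the stages in WT (162 without E3.5 WT 13, 18 without 16, 7 without 20, 11 without 21, 70 without 22; 3, 0 and 2 without E3.75 WT 1, 2 and 3) and 0 to 17 in MUT (17 without E3.5 MUT 10, 3 without 23 and 1 without 18, 2 or 24; 5, 0, 1 and 1 without E3.75 MUT 1, 2, 4 and 5). Imprinted medians in the ICM were 0.40 to 0.66, with the call lost without MUT 10, 18 or 24 or WT 13, 16 or 22 (adjusted p 0.0503 to 0.137). The EPI share differed by −32.7 to −17.6 points without an embryo, at exact p from 0.0667 to 0.100, the smallest these numbers of embryos can give. OXPHOS medians without an embryo reached −0.24 to 0.28 in the ICM (−1.11 by limma-voom on single cells with the letter), −0.39 to −0.0761 between the stages in MUT and −0.22 to 0.20 in the stage interaction, with camera's direction turned without E3.5 MUT 10 in each (median 0.28, adjusted p = 0.00167 in the ICM; −0.39, 2.66e-04 between the stages, where the median kept its sign; −0.22, 0.366 in the interaction). What depth limits was not simulated: a fold of 4 was recovered for 11 of 100 simulated genes both in the ICM and between the lineages in WT, whose cells are deeper, and for 4 of 100 in each interaction.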

Other observations

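The comparisons of X-linked genes and of single cells in this part were chosen only after the results were seen.

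Means of FGF/ERK targets lay apart in opposite directions between EPI and PrE, with no member past the threshold over all genes. In WT, Dusp4, an ERK phosphatase, averaged 4.91 ± 4.19 CPM in EPI and 282 ± 190 in PrE, whereas Etv5, an ETS factor, averaged 388 ± 78.3 and 42.8 ± 29.2 (n = 3 each), and Egr1 361 ± 91.2 and 882 ± 331 (edgeR adjusted p = 0.224, 0.224 and 0.255). In MUT, Dusp4 averaged 38.2 ± 48.5 and 251 ± 86.0 and Etv5 461 ± 131 and 71.5 ± 47.2 (n = 4 each; adjusted p = 0.352 and 0.218). The list had medians of −0.20 in WT (camera adjusted p = 0.616) and −0.01 in MUT (mean 0.31, adjusted p = 0.447), and in WT 1 member passed as higher and 2 as lower adjusted over the list alone.

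Some regulators of DNA methylation also had means apart in opposite directions, with none of the genes named in this paragraph past the threshold. As a list they had a median of 0.22 in WT (camera adjusted p = 0.503) and 0.51 in MUT (0.164). In WT the list passed in 0 of 9 alternatives. In WT, Zfp57, a zinc finger protein that maintains imprints, averaged 223 ± 68.2 CPM in EPI and 27.5 ± 9.70 in PrE (edgeR adjusted p = 0.120), and Dnmt3a 7.72 ± 5.24 and 694 ± 923 (adjusted p = 0.235). Among STAT3 targets, Klf5 averaged 104 ± 3.77 in EPI and 280 ± 52.5 in PrE, and Myc 290 ± 135 and 37.8 ± 21.8 (adjusted p = 0.138 and 0.224). In trophectoderm markers, Fabp3, a fatty acid binding protein, averaged 28.6 ± 9.95 and 325 ± 343 in WT and 14.7 ± 19.1 and 313 ± 260 in MUT (adjusted p = 0.287 and 0.0818).

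X-linked genes were lower than autosomal genes in MUT EPI relative to WT: the median log2 fold change of 260 X-linked genes lay −0.219 from that of 7604 autosomal genes, and −0.169 in PrE (267 and 7556 genes). The WT embryos at E3.75 include females and the MUT embryos do not, so a dose difference of the X, not yet balanced by inactivation, is a candidate explanation. With embryo sex as a covariate the difference was 0.0655 in EPI (0.109 with the letter) and 0.175 in PrE, which is consistent with sex, although the covariate rests on 1 male WT embryo. An effect of the Stat3 genotype stays open: in E3.5 ICM, where both genotypes hold both sexes, the difference was −0.256 with sex as a covariate and −0.00937 without it.

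Cell 4 with the letter G of MUT embryo 10 and cell 4 with the same letter of WT embryo 20 had correlated log2 CPM (Pearson 0.786 across genes, which are not independent replicates), the closest of all pairs of cells from different genotypes; the closest of all pairs reached 0.803, in WT EPI of embryo 1. The WT cell, which is among the low-quality cells, held 167101 counts, 59.8 CPM of Y-linked genes, 114 CPM of Xist and 1 Stat3 count. The MUT cell held 6992785 counts, 0.858 CPM of Y-linked genes, 3.58 CPM of Xist and 283 Stat3 counts.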
